A study of Mus musculus with 48 samples.

How the data were processed

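The series holds 48 RNA-seq libraries from mouse conceptuses collected at embryonic day 14.5, 24 from fetal liver and 24 from placenta. Per the labels' protocols, embryos came from superovulated females. Cultured embryos were kept singly in 2 uL drops under 5% oxygen, in medium with VEGF, IGF1, IGF2, PDGF and GCSF or in the same medium without them. Blastocysts were transferred on day 4 and the tissues were taken 10 days later, with 1 ug of total RNA going into each library. Each tissue has 6 libraries from embryos cultured with the growth factors and cytokines (called GF here), 6 from embryos cultured without them (control) and 12 from embryos that developed in vivo. The series description says developed in vitro for the last group where the sample labels say in vivo, and the sample labels were followed. The in vivo libraries carry 2 title prefixes, G and A, with 6 libraries per tissue each. The labels do not say how the prefixes differ. Nor do they say whether embryos of the in vivo group were also transferred. Each GF and control group has 3 males and 3 females, and each in vivo group has 6 males and 6 females.

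The authors deposited 1 table of raw counts per library. Per the submitters' processing notes, reads were trimmed with Trim Galore, aligned with STAR and counted with featureCounts on GRCm38 (mm10), with no versions, strand setting or annotation release named. Without a stated strand setting, overlapping and antisense genes cannot be told apart. The handling of reads that match several places is not recorded either, so values of genes with near-identical copies are uncertain. Among the genes named below this applies to the Serpina1, prolactin and paired immunoglobulin-like receptor families and to Prps1l3 and Eif3j2. Each table lists 55421 gene identifiers, of which 55154 (99.5%) paired with a symbol. The tables hold 37 mitochondrially encoded genes with 0 counts in all libraries, so mitochondrial transcripts could not be examined. The authors also deposited 6 result tables made with DESeq2, per the file headers, holding a log2 fold change, a p-value and an adjusted p-value for each comparison of groups within a tissue. These were read only for a side-by-side count. Their headers do not state the direction, and across genes each correlated negatively with the fits here (Spearman -0.949 to -0.985), so the direction was inferred from this and their signs were turned.

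Counts were analysed in R 4.3.3 with edgeR 4.0.16. Within each tissue all 24 libraries entered 1 model with group and sex. Genes were filtered with filterByExpr, library sizes were scaled by TMM, and the quasi-likelihood F test was used with Benjamini-Hochberg adjustment over 15996 liver and 16831 placenta genes. A gene was called at an adjusted p under 0.05. The groups give 3 comparisons per tissue, written as first group minus second group. Further edgeR tests asked whether an effect differed between males and females, between placenta and liver, and between in vivo libraries of the 2 prefixes. Values per gene are CPM, each count as a rate over its TMM-scaled library total, as mean ± SD over the libraries of a group, and log2 fold changes carry the standard error (SE) of the fit. Adjusted p-values in the text are from edgeR's quasi-likelihood test unless another tool is named.

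The gene lists, the design, most alternatives and the rule for naming genes were written before the data were examined. There were 41 lists of pathways and cell type markers with 742 genes, of which 6 were not found by symbol. A list was tested where 3 or more members were measured. Lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2, once with a preset correlation of 0.01 and once with an estimated correlation, and with fry. Member counts are given over all genes tested and adjusted over the list alone. The naming rule took, per comparison, the 6 higher and 6 lower called genes with the largest fold change at an average log2 CPM of 1 or more. It added the 4 higher and 4 lower genes with the lowest p and up to 3 called members of each list. Predicted genes and clones were counted but not named. With fewer than 10 called genes, the 10 with the lowest p were taken and are given as not passing. For the interaction-type tests the 5 with the lowest p were taken. Not all genes taken by the rule are named below. In addition, 16 genes of the growth factor axis, the sex chromosomes and tissue identity were always examined.

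Total counts per library ranged from 22046122 to 36631481. The tests were run first on simulated counts drawn from the real means and library sizes. For liver GF minus control, 50.7% of genes changed 1.5-fold, 80.6% of those changed 2-fold and 97% of those changed 4-fold were called, with 4 false calls among 15872 genes. For placenta GF minus control these shares were 38.8%, 73.1% and 93.9%, with 8 false calls among 16724 genes. Liver GF minus in vivo gave 61.2%, 83.6% and 98.5%, and placenta GF minus in vivo gave 49.3%, 79.1% and 98.5%. An unchanged control minus in vivo comparison gave 0 calls in both tissues. The simulated genes were drawn independently, so these shares and false calls do not cover variation that genes of 1 library share.

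Alternatives were DESeq2 1.42.0, its size factors in edgeR, no filter and a stricter filter on low counts, no sex term, only the groups compared, each title prefix alone, each sex alone, the title number as a block, sequencing lane as a term for liver, a fold limit, and each library left out in turn. Those added after the data were seen removed each library's trend on transcript length, left out doubted libraries, added a yolk sac score as a term, added lane as a term to the liver test of the prefixes, or split the conceptus numbers at random to weigh the agreement of the tissues. A library was doubted when a chosen marker list lay more than 3 median absolute deviations above the tissue's median, which held for 3 liver and 2 placenta libraries. The lists used were pancreas and gut, and muscle, for liver. For placenta they were yolk sac endoderm, decidua, uterine natural killer cells, muscle and macrophages. Liver control female 5 lay 3.43 such deviations above the median in the decidua list, which was not used for liver, and was not doubted. Lane was read from the names of the count tables. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.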

Results

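Fetal livers and placentas were profiled by RNA sequencing at embryonic day 14.5 from 3 kinds of mouse conceptus. In 1 kind the embryos had been cultured to the blastocyst stage with a mixture of growth factors and cytokines (GF, 6 libraries per tissue). In the others they had been cultured without the mixture (control, 6 libraries per tissue) or had developed in vivo (12 libraries per tissue). Liver libraries held 22046122 to 33157775 counts and placenta libraries 24060764 to 36631481, and the 10 most abundant genes took 11.2% to 17.3% of a liver library and 9.55% to 22.4% of a placenta library. Xist, the transcript of the inactive X chromosome, lay between 95.7 and 249 CPM in livers labelled female and at 0.163 CPM or less in livers labelled male. Ddx3y, on the Y chromosome, lay between 34.1 and 66.6 CPM in male livers and between 52.6 and 77.6 CPM in male placentas. Among female livers the highest Ddx3y value was 2.11 CPM, in GF female 6.

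The first liver comparison asks what the mixture adds to culture. GF livers had higher Pdpr, a regulatory subunit of pyruvate dehydrogenase phosphatase, at 20.5 ± 2.66 CPM against 11.3 ± 3.20 CPM in control livers (SD, n = 6 and 6), a log2 fold change of 0.89 (SE 0.146, adjusted p = 0.00819). Hipk2, a nuclear protein kinase, rose by 0.83 (149.6 ± 42.5 against 84.8 ± 30.5 CPM, adjusted p = 0.0358), and Usp9x, an X-linked deubiquitinase, by 0.63 (adjusted p = 0.0116). Rrp1, which takes part in ribosomal RNA processing, fell from 221 ± 5.07 to 182.8 ± 8.90 CPM, a log2 fold change of -0.27 (adjusted p = 0.00819), and all 6 GF livers lay below the control mean. Lpl, lipoprotein lipase, fell from 159.4 ± 26.3 to 99.1 ± 19.9 CPM (log2 fold change -0.68, adjusted p = 0.0386). Pdpr (ENSMUSG00000033624) lies on chromosome 8 at 111094630 to 111137074 and Rrp1 (ENSMUSG00000061032) on chromosome 10 at 78400384 to 78413043 of GRCm38.

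In all, 179 genes differed between GF and control livers, 124 higher and 55 lower, with a median absolute log2 fold change of 0.375. Only 5 of them changed by 1 or more on the log2 scale, and 39 were predicted genes or clones. Other genes that rose were Rab43, a small GTPase (0.91), Klhl11, an adaptor of a ubiquitin ligase (0.72), the nuclear receptor Nr2c2 (0.66), the splicing factor Mbnl3 (0.52), Prps1l3 (0.44) and the collagen galactosyltransferase Colgalt1 (0.30). Genes that fell included Ccdc18 (-0.91), the pore-forming protein Gsdme (-0.77), the nucleosome-binding protein Hmgn5 (-0.69), the anion channel subunit Lrrc8a (-0.65), Pick1 (-0.54) and the cochaperone Dnajc21 (-0.50), with adjusted p-values from 0.00819 (Lrrc8a) to 0.0452 (Pick1).

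**Figure D1:**
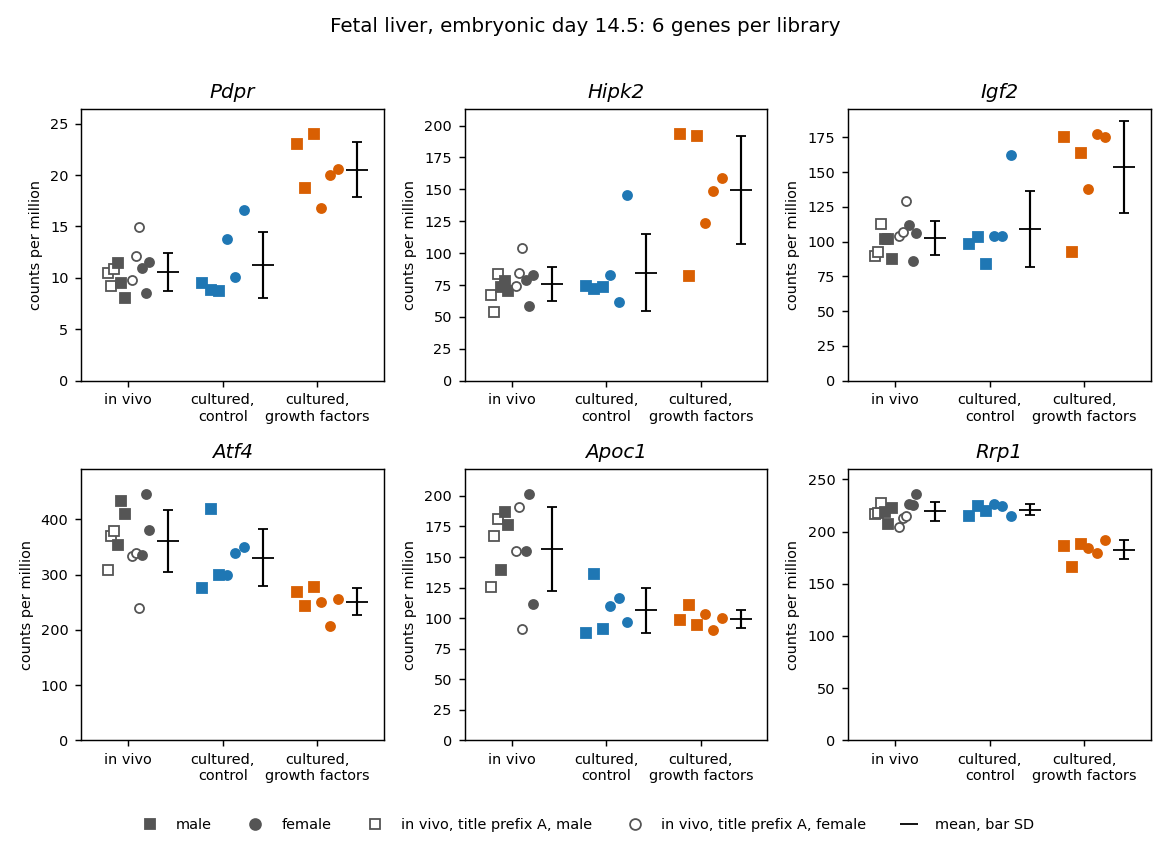
CPM of 6 genes in each fetal liver library, by group, with squares for males, circles for females, open symbols for in vivo libraries of title prefix A, and the mean with SD beside each group. Pdpr averaged 20.5 CPM in GF livers against 11.3 in control livers, while 1 GF male and 1 control female lie apart from the rest of their group in Hipk2 and Igf2.

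Among the gene lists, cholesterol synthesis had 1 member past the test over all genes, Dhcr24, which reduces the sterol side chain (332.1 ± 26.1 against 267.9 ± 26.6 CPM, log2 fold change 0.31, adjusted p = 0.025). Adjusted over the list alone, 7 of its 24 members passed, all higher, and its median log2 fold change was 0.12 (camera adjusted p = 0.000134 with a preset correlation, adjusted p = 0.938 with an estimated correlation). The list of the endoplasmic reticulum stress and amino acid response had 1 of 22 members past the test, the transcription factor Atf5, which fell by 0.47 on the log2 scale (adjusted p = 0.0476). In the 12 fits without 1 library of these groups, Gsdme, Rab43 and Ccdc18 kept an adjusted p under 0.05 in 9, 8 and 8, Dhcr24 and Klhl11 in 5 each, Atf5, Lpl, Hipk2 and Nr2c2 in 4 each and Pick1 in 3, and the other named genes in all 12. Members of the cell cycle list lay higher in 22 of 25 cases (median 0.11, preset adjusted p = 0.00164), definitive erythroid genes in 19 of 21 (median 0.14, p = 0.00414) and nuclear genes of oxidative phosphorylation in 32 of 40 (median 0.13, p = 0.00414), with 0 of these members past the test over all genes. Interferon-response genes lay lower in 18 of 21 cases (median -0.38, preset adjusted p = 0.0206). With an estimated correlation each of these 4 lists had an adjusted p of 0.938. None of the examined growth factor genes passed: Igf2 had a log2 fold change of 0.50 (adjusted p = 0.061) and Vegfa of -0.18 (adjusted p = 0.502). Csf3, which encodes GCSF, was too low to test, with at most 1 count in any liver library.

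The count of 179 depended on the libraries and settings used: with only the 12 GF and control livers edgeR called 0 genes (2353 at an unadjusted p under 0.05), without the 3 doubted livers 72, with no filter on low counts 35, and with in vivo prefix G alone 318. Males alone, whose GF and control libraries were all in 1 lane, gave 16 genes, and females alone, whose GF and control libraries were all in the other lane, gave 0 (868 at an unadjusted p under 0.05). Leaving out 1 library gave 71 genes without control 1, 25 without control 2, 35 without control 3, 17 without control 5, 290 without control 6, 74 without GF 1, 51 without GF 3, 49 without GF 5 and 366 without GF 6. The excess of higher genes moved as well. With no filter 15 were higher and 20 lower, with prefix G alone 170 and 148, without GF 1 37 and 37, and with DESeq2 394 and 285.

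The most genes were called between GF livers and livers that developed in vivo. Genes of the hepatocyte list fell: 9 of 31 measured members were lower and 1 was higher over all genes tested. Apoc1, an apolipoprotein, went from 156.7 ± 34.3 CPM in vivo (n = 12) to 99.4 ± 7.10 CPM in GF livers (n = 6), a log2 fold change of -0.66 (SE 0.135, adjusted p = 0.00367), and Serpina1a and Apoa1 had log2 fold changes of -0.57 and -0.59 (adjusted p = 0.0135 and 0.0288). The stress-response regulators Atf4, Atf5 and Ddit3 fell by 0.53, 0.51 and 0.47 on the log2 scale, with Atf4 at 250.7 ± 24.6 CPM in GF livers against 360.6 ± 56.6 CPM in vivo (adjusted p = 0.00267). Igf2, a fetal growth factor, rose from 102.5 ± 12.4 to 153.7 ± 33.4 CPM, a log2 fold change of 0.58 (SE 0.114, adjusted p = 0.00252), and lay above the in vivo mean in 5 of 6 GF livers. The megakaryocyte genes Tubb1 and Vwf rose by 0.59 and 0.55 (adjusted p = 0.00326 and 0.0104).

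Of 15996 genes tested 1609 differed, 979 higher and 630 lower, with a median absolute log2 fold change of 0.303. Among the 1609, 27 changed by 1 or more on the log2 scale. Genes with a low p that rose included Vps33a, of the endosome-fusion machinery (0.31), Kctd10 (0.63), Virma, of the RNA methylation complex (0.39), and Pdpr (0.97), which is also among those higher than in control livers. Further genes that rose were Klhl11 (0.97), Hipk2 (0.99) and the focal adhesion protein Vcl (0.78). Genes with a low p that fell included Rrp1 (-0.26), Pdrg1 (-0.40) and the prefoldin subunit Pfdn2 (-0.34). Among genes with a name and an average log2 CPM of 1 or more, the largest falls were in the microRNA host transcript Mir142hg (-1.49), the lipid droplet enzyme Hsd17b13 (-1.22) and the lipase inhibitor Angptl8 (-0.94). Adjusted p-values of these genes ran from 0.000121 (Vps33a) to 0.048 (Hsd17b13).

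Adjusted over the list alone, 19 hepatocyte genes were lower and 1 higher, with a median log2 fold change of -0.45. The preset camera test gave an adjusted p of 1.73e-07, and adjusted p = 0.927 with an estimated correlation. Albumin, Alb, had a log2 fold change of -0.33 that did not pass (adjusted p = 0.216). Collagen and matrix genes moved the other way, with 21 of 23 higher (median 0.22). Their preset camera adjusted p was 0.0184, and adjusted p = 0.927 with an estimated correlation. The megakaryocyte list had 5 of 14 members higher over all genes tested, Tubb1, Vwf and Thbs1 among them, and a median of 0.27 (preset adjusted p = 0.00103, adjusted p = 0.927 with an estimated correlation). Of 33 genes of the growth factor axis 5 rose, among them Igf2, the insulin receptor substrate Irs1 (0.74, adjusted p = 0.00391), the vascular receptors Flt4 (0.43) and Kdr (0.37). The preset camera test of this list gave an adjusted p of 0.105. Endothelial genes rose in 3 of 15 cases (Stab2, Cdh5 and Kdr) and macrophage genes in 3 of 15 (Adgre1, Mrc1 and Csf1r), with preset adjusted p-values of 0.074 and 0.195 for the lists and adjusted p = 0.927 with an estimated correlation for both.

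Nuclear oxidative phosphorylation genes had 5 of 40 members lower (Ndufb3, Ndufa5 and Cycs among them; median -0.07, preset adjusted p = 0.0406, adjusted p = 0.95 with an estimated correlation). With in vivo prefix G alone that list's direction turned and its adjusted p was 0.953. Fatty acid oxidation genes fell in 3 of 21 cases, with Fabp1 at -0.55 and Acadm at -0.27, and their regulator Ppara rose by 0.46 (adjusted p = 0.021). The metallothioneins Mt2 and Mt1 fell by 0.54 and 0.44, and G6pdx, of the pentose phosphate pathway, rose by 0.33 (adjusted p = 0.024), which makes 3 of 20 oxidative stress genes past the test. Among 41 imprinted genes 3 rose and 3 fell, with Igf2 and its neighbour H19 moving apart (0.58 and -0.27, adjusted p = 0.0249 for H19). Cell cycle genes changed in 3 of 25 cases, with Mcm5 and Bub1b higher (0.32 and 0.23) and Birc5 lower (-0.25, adjusted p = 0.0322). Of 21 erythroid genes 1 rose, the anion exchanger Slc4a1 (0.35, adjusted p = 0.0215). These member counts stand beside 1609 called genes of all 15996 tested, so small counts do not mark a list as changed. The preset camera adjusted p was 0.359 for fatty acid oxidation, 0.463 for both oxidative stress and cell cycle, and 0.789 for imprinted genes.

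**Figure D2:**
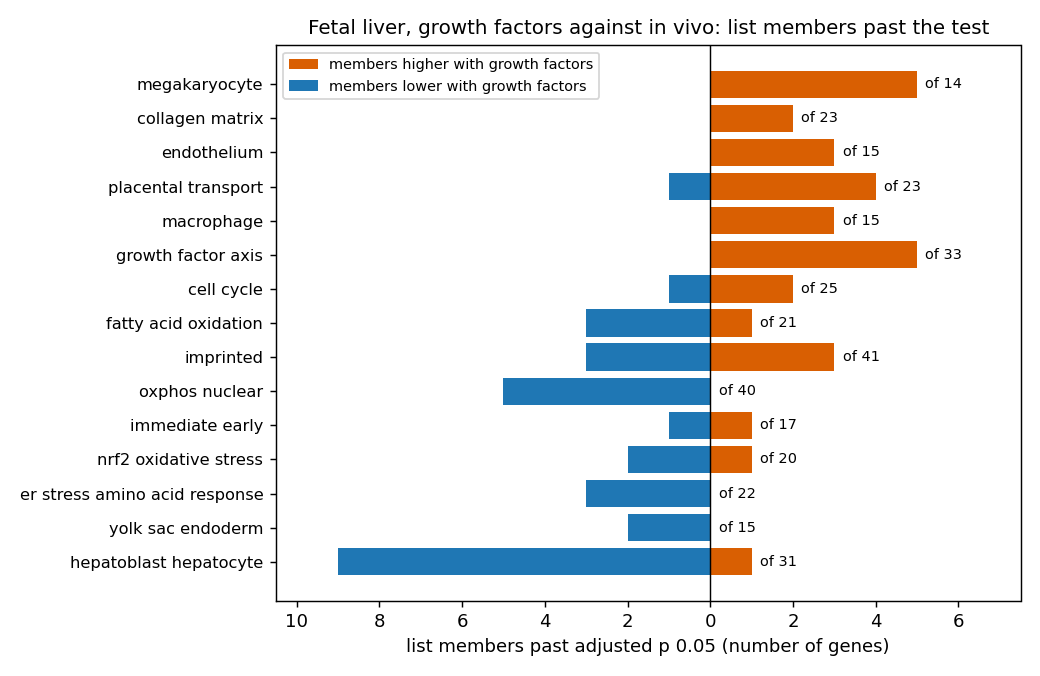
Number of list members higher (right of 0) or lower (left of 0) at an adjusted p under 0.05 over all genes tested in fetal liver, GF minus in vivo, with the number measured beside each bar. Only lists with more than 1 such member are drawn. The hepatocyte list has 9 members lower and 1 higher of 31, and the megakaryocyte list has 5 higher of 14.

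Transcript length went along with this contrast. Across 15988 genes with a length, which are not independent replicates, the log2 fold change had a Spearman correlation of 0.243 with length, and the median longest transcript was 4313 bases for genes that rose and 2244.5 for genes that fell. Of the 6 lists past the preset test in this contrast, 0 passed with an estimated correlation or with fry. The count of 1609 became 380 with in vivo prefix A alone, 904 without a filter on low counts, 403 in males alone and 0 in females alone (2255 at an unadjusted p under 0.05), 913 without GF 1, 820 without GF 3 and 893 without GF 5. Of the genes named, Birc5, Csf1r and Hsd17b13 kept an adjusted p under 0.05 in 13, 9 and 5 of the 18 fits without 1 library, and the others in 15 or more.

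Control livers were also compared with in vivo livers. No gene passed in edgeR, the lowest adjusted p being 0.159, while 2503 genes had an unadjusted p under 0.05 and DESeq2 called 164, 47 higher and 117 lower. The genes with the lowest p, given as not passing, included Pdk4, a kinase that shuts down pyruvate dehydrogenase (5.32 ± 1.28 CPM against 3.20 ± 0.433, log2 fold change 0.73), Tlr2, a receptor for bacterial lipoproteins (0.74), the matrix protease inhibitor Timp3 (0.49), Krt5 (2.31, at 1.62 CPM in control livers) and the heme-responsive repressor Bach1 (0.28), each with an adjusted p of 0.159. Without in vivo 6, edgeR called 2 genes.

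In this contrast some lists held members that passed when adjusted over the list alone, although 0 passed over all genes. Interferon-response genes had 9 of 21 such members, all higher, with all 21 log2 fold changes above 0 and a median of 0.59. Hepatocyte genes had 9 of 31, all lower (median -0.29), genes of liver metabolism 7 of 19, all lower (median -0.51), and cholesterol synthesis 6 of 24, all lower (median -0.14). Oxidative phosphorylation genes lay lower in 40 of 40 cases with a median of -0.19, and 0 passed over the list alone. The preset camera adjusted p-values of these 5 lists ran from 1.21e-13 (oxidative phosphorylation) to 1.9e-05 (liver metabolism), and adjusted p = 0.429 with an estimated correlation for each. Among lists of other cell types stellate and mesenchyme genes lay higher in 15 of 15 cases (median 0.18, preset adjusted p = 0.00281), macrophage genes in 14 of 15 (median 0.18, p = 0.00281), collagen and matrix genes in 21 of 23 (median 0.31, p = 7.03e-05) and muscle genes in 9 of 11 (median 0.64, p = 0.00232), while definitive erythroid genes lay lower in 18 of 21 (median -0.17, p = 0.000294) and B lymphoid genes in 10 of 12 (median -0.60, p = 0.00109). With an estimated correlation the adjusted p-values of these 6 lists ran from 0.429 to 0.479. Among 38 lists 18 passed the preset test and 0 passed with an estimated correlation (lowest adjusted p = 0.429) or with fry. Several lists, among them interferon response, cholesterol synthesis and oxidative phosphorylation, had medians of opposite sign in GF minus control. The same control livers enter both contrasts with opposite sign, so a chance deviation of these livers would give that pattern. The opposite signs therefore do not show that the mixture reverses an effect of culture. Across genes the Spearman correlation of log2 fold change with transcript length was 0.377. The shift of the oxidative phosphorylation list was not separated from this trend here.

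The 2 culture groups were then compared in how they differ from the same in vivo livers. Of the 1609 genes called in GF minus in vivo, 1362 (84.6%) had the same sign in control minus in vivo, against 66.6% of all 15996 genes, and 0 genes were called in both by edgeR. Pearson's correlation of the log2 fold changes across genes was 0.421, where unchanged groups set against the same in vivo livers gave a mean of 0.329 in 20 simulations, ranging from 0.297 to 0.353. The covariance was 0.0282 against a simulated mean of 0.0172. The simulations drew each gene independently and so lack the variation that genes of 1 library share. Their range is therefore too narrow to tell whether the observed values exceed chance. With the in vivo libraries divided so that the contrasts shared none, the covariance was -0.0245 in 1 arrangement and 0.0144 in the other, and the same sign held for 55.5% of 1293 and 87.2% of 508 called genes.

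Placentas were compared in the same way. Between GF and control placentas edgeR and DESeq2 each called 0 genes, with 1987 genes at an unadjusted p under 0.05 in edgeR and 2114 in DESeq2. The genes with the lowest p included Rasal2, a Ras GTPase activator (14.4 ± 0.987 against 10.3 ± 2.50 CPM), Plac1, a trophoblast membrane protein (92.4 ± 7.98 against 121.8 ± 16.8 CPM), Tex19.1 (log2 fold change -0.32), Evpl (0.75) and Galk1 (-0.48), each with an adjusted p of 0.414. Igf2r, the receptor that clears IGF2, and Pdgfra, a PDGF receptor, had log2 fold changes of 0.45 and 0.46, with the same adjusted p of 0.414. Csf3 was too low to test in placenta as well, with at most 3 counts in a library.

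Genes of endoderm lay lower in GF than control placentas. Of 18 measured yolk sac endoderm genes 17 lay lower in GF placentas, with a median log2 fold change of -2.93, and 14 passed when adjusted over the list alone. Of 30 hepatocyte genes 27 lay lower (median -3.09), of which 25 passed over the list alone. Neither list had a member past the test over all genes, and 10 yolk sac genes and 12 hepatocyte genes also stand on other lists. Of single genes chosen after their values were seen, on library totals, Afp, alpha-fetoprotein, had a median of 75.4 CPM in GF placentas (range 18.4 to 631.9), 1725 in control placentas (221.5 to 6628) and 683.9 in vivo (65.5 to 16480). Cubn, the endocytic receptor cubilin, had medians of 4.75, 25.4 and 19.7 CPM in the same order. The preset adjusted p-values were 1.63e-09 (yolk sac) and 4.68e-14 (hepatocyte), and adjusted p = 0.505 with an estimated correlation for both.

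**Figure D3:**
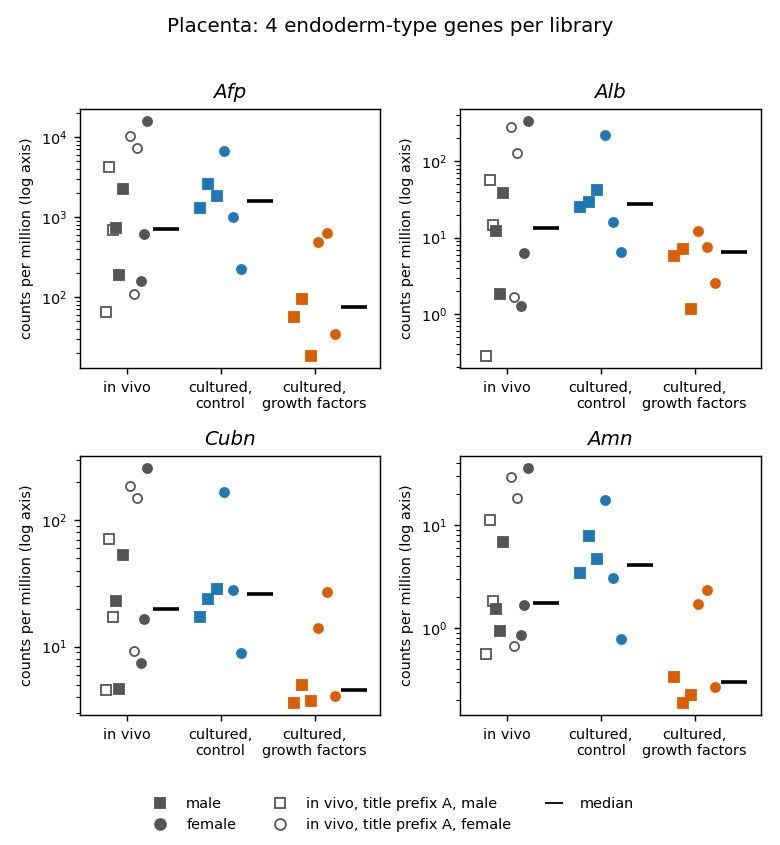
CPM on a log axis of 4 endoderm genes in each placenta library, by group, with squares for males, circles for females, open symbols for in vivo libraries of title prefix A, and a bar at each group's median. The median of Afp was 75.4 CPM in GF, 1725 in control and 683.9 in in vivo placentas on library totals, and the groups overlap in each gene.

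In the same comparison 39 of 40 nuclear oxidative phosphorylation genes lay lower in GF placentas, with a median of -0.23, and 22 passed over the list alone but 0 over all genes (preset adjusted p = 1.6e-16, adjusted p = 0.505 with an estimated correlation). Megakaryocyte genes lay higher in 13 of 13 cases (median 0.41) and syncytiotrophoblast genes in 13 of 14 (median 0.26), with 0 members past the test in either, preset adjusted p-values of 0.0014 and 0.0032, and adjusted p = 0.605 and 0.676 with an estimated correlation. Across 16822 genes the Spearman correlation of log2 fold change with transcript length was 0.458. The values given here do not separate the shift of the oxidative phosphorylation list from this trend.

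Control placentas differed from in vivo placentas in 3 genes, all higher. Prl7a1, a prolactin-family hormone of trophoblast, was at 278.5 ± 81.9 CPM (n = 6) against 119.3 ± 36.9 CPM (n = 12), a log2 fold change of 1.22 (SE 0.179, adjusted p = 0.00482), and was above the in vivo mean in 6 of 6 control placentas. Endou, a placental endoribonuclease, was at 4.88 ± 2.48 against 1.08 ± 0.446 CPM (log2 fold change 2.18, adjusted p = 0.0462). Pirb, an inhibitory receptor of myeloid cells, was at 0.724 ± 0.382 against 0.246 ± 0.082 CPM (1.54, adjusted p = 0.00482). Prl7a1 (ENSMUSG00000006488) lies on chromosome 13 at 27633366 to 27642493. Among the next genes by p, Fst, the activin antagonist follistatin, had a log2 fold change of 1.26 and Klk8 of 1.18, both with an adjusted p of 0.141.

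Macrophage genes lay higher in control than in vivo placentas in 12 of 12 cases, with a median log2 fold change of 0.93, and 7 passed over the list alone. This list passed fry (adjusted p = 0.0448) and the preset test (adjusted p = 7.2e-07), with adjusted p = 0.268 with an estimated correlation. Control female 6 had a macrophage score 1.39 log2 units above the mean of all placentas, over 3 median absolute deviations from the tissue's median. Cell cycle genes lay higher in 25 of 25 cases (median 0.37), of which 5 passed over the list alone (preset adjusted p = 9.8e-12, adjusted p = 0.681 with an estimated correlation). Trophoblast hormone genes had 1 of 23 members past the test, Prl7a1, and 3 over the list alone (preset adjusted p = 0.106).

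These calls depended on the libraries used. Without control 6 edgeR called 0 genes, with Prl7a1 and Pirb at an adjusted p of 0.053 and log2 fold changes of 1.08 and 1.27, without in vivo 2 it called 5 and without in vivo A6 it called 7, while Endou kept an adjusted p under 0.05 in 4 of the 18 fits without 1 library. DESeq2 called 78, 45 higher and 33 lower, and in vivo prefix G alone gave 9, 3 higher and 6 lower. Prefix A alone, males alone and females alone gave 0 (1475, 1560 and 1878 genes at an unadjusted p under 0.05).

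GF placentas differed from in vivo placentas in 21 genes, 20 higher and 1 lower. Prl7a1 was at 324.3 ± 76.1 CPM against 119.3 ± 36.9 CPM, a log2 fold change of 1.43 (SE 0.179, adjusted p = 0.000554), and Endou at 5.94 ± 4.28 against 1.08 ± 0.446 CPM (2.49, adjusted p = 0.00631). Fgd1, an activator of the GTPase CDC42, was at 28.5 ± 4.02 against 14.2 ± 4.18 CPM (1.02, adjusted p = 0.000697), and Rasal2 rose by 0.59 (adjusted p = 0.00781). Cd74, the invariant chain of MHC class II, rose by 0.93 (adjusted p = 0.0121) and the scavenger receptor Stab1 by 0.87 (adjusted p = 0.0314), while macrophage genes lay higher in 10 of 12 cases (median 0.37, preset adjusted p = 0.0319, adjusted p = 0.594 with an estimated correlation) with 0 past the test over all genes or over the list alone. Prom2 rose by 1.51 (adjusted p = 0.0301), and the 1 gene that fell was Smim19 (-0.35, adjusted p = 0.0371). The placental lactogen Prl3b1 had a log2 fold change of -0.39 that did not pass (adjusted p = 0.188).

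**Figure D4:**
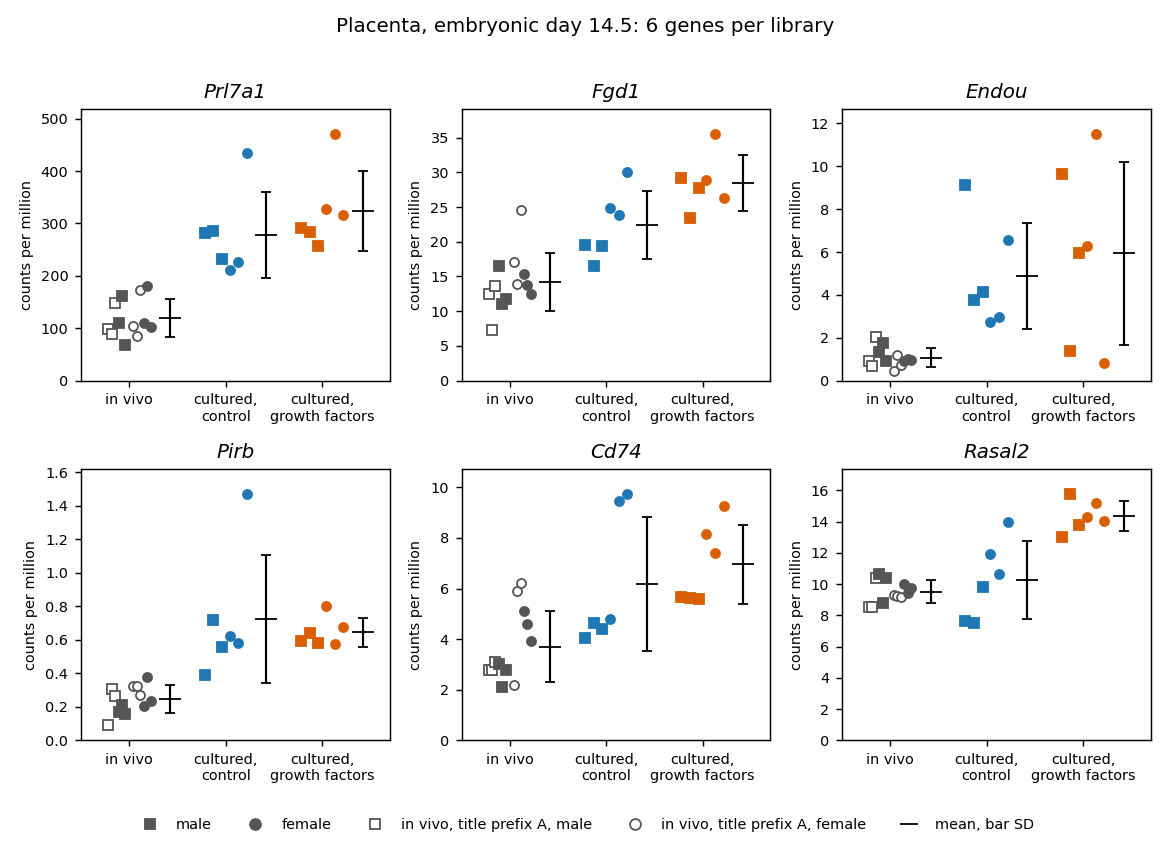
CPM of 6 genes in each placenta library, by group, with squares for males, circles for females, open symbols for in vivo libraries of title prefix A, and the mean with SD beside each group. Prl7a1 averaged 324.3 CPM in GF, 278.5 in control and 119.3 in in vivo placentas.

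Yolk sac endoderm genes lay lower in GF than in vivo placentas in 17 of 18 cases (median -3.28, 16 past the test adjusted over the list alone) and hepatocyte genes in 30 of 30 (median -3.23, 26 over the list alone), again with 0 over all genes. Oxidative phosphorylation genes lay lower in 39 of 40 cases (median -0.25, 25 over the list alone). These 3 lists had preset adjusted p-values of 3.28e-09, 5.51e-12 and 3.98e-14, and adjusted p = 0.594 with an estimated correlation for each. Cell cycle genes lay higher in 23 of 25 cases (median 0.26) and decidual genes in 12 of 14 (median 0.38), with 0 over the list alone (preset adjusted p = 0.000163 and 0.00696, adjusted p = 0.594 with an estimated correlation for both). Across genes the Spearman correlation with transcript length was 0.441, and the oxidative phosphorylation shift was not separated from this trend here.

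The count of 21 was 807 with DESeq2, of which 246 were higher, 53 with only the 18 libraries of the 2 groups, 8 with the length trend removed, 2 with the yolk sac score as a term, 1 with in vivo prefix A alone, and 0 in each sex alone (2003 genes in males and 2021 in females at an unadjusted p under 0.05). It was 10 without GF 1, 9 without GF 2, 11 without GF 3, 10 without GF 5, 11 without GF 6, 12 without in vivo 3, 9 without in vivo 5, 36 without in vivo A2, 10 without in vivo A3 and 50 without in vivo A6. Prom2, Stab1 and Smim19 kept an adjusted p under 0.05 in 10, 9 and 6 of the 18 fits without 1 library.

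The 3 genes called in control placentas, Prl7a1, Endou and Pirb, were all called in GF placentas in the same direction, where 0.00356 shared genes would fall together by independent draws. Both lists are set against the same in vivo placentas, and 20 simulations of unchanged groups shared 0 calls but called at most 1 gene, so they give no chance value for this overlap. Pearson's correlation across genes was 0.423 against a simulated mean of 0.325, and the covariance 0.0482 against 0.0178. Genes were drawn independently here too, so the simulations cannot tell whether these differences exceed chance. With the in vivo placentas divided between the contrasts, the covariance was 0.0197 and 0.029, and 0 and 1 genes were called in both.

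Across tissues, 1297 of the 1563 genes called in liver GF minus in vivo and measured in placenta had the same sign there (83%), against 65.5% of all 14637 genes, and 1 was called in both. Both contrasts went along with transcript length (0.243 in liver and 0.441 in placenta), and with the length trend removed the same sign held for 78% of 1486 called genes against 60.5% of all. With the same-numbered liver and placenta kept together, 20 random splits of the 18 conceptus numbers gave 32.2% to 85.9% (median 53.9%) for the 1609 liver genes with the lowest p, and 1 of the splits reached 83% or more. For GF minus control the same sign held for 99 of 177 called liver genes (55.9%) against 47.7% of all genes. A direct test of placenta against liver called 19 genes whose GF minus control effect differed, 4 more positive and 15 more negative in placenta. Among genes with a name the lowest p belonged to Qprt, of NAD synthesis, at -1.47 in placenta and 0.09 in liver (difference -1.56, SE 0.234, adjusted p = 0.0192), followed by the FGF coreceptor Klb (difference -1.48), the zinc transporter Slc39a5 (-2.74) and the amino acid transporter Slc36a2 (-2.17), each with an adjusted p of 0.0377. DESeq2 called 506 such genes, and a fit with the conceptus number as a block called 1.

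Effects did not differ detectably between male and female conceptuses in edgeR, which called 0 genes in all 6 comparisons. In simulated counts for GF minus control, genes changed 4-fold in GF males only were called in 77% of cases in liver and 73% in placenta. Smaller sex differences were not simulated. In liver 505, 348 and 761 genes had an unadjusted p under 0.05 for GF minus control, control minus in vivo and GF minus in vivo, and DESeq2 called 0, 4 and 2. In placenta the counts were 1725, 1878 and 837, and DESeq2 called 63, 164 and 1. The lowest p in placenta GF minus control belonged to Itga2, an integrin subunit, at 0.91 in males and -0.39 in females, and Nrp2, a VEGF coreceptor, at 0.68 and -0.71 (adjusted p = 0.295 for both). In placenta control minus in vivo they belonged to Ltbp4 (0.70 and -0.62) and Dnajb4 (-0.56 and 0.44), with an adjusted p of 0.133.

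In vivo livers of title prefix A differed from those of prefix G in 44 genes, 12 higher and 32 lower. All 6 livers of prefix A were in lane 2 and 4 of 6 of prefix G in lane 1, so that prefix and lane are largely confounded, and with lane as a term 1 of the 44 was called (2013 genes at an unadjusted p under 0.05). Genes with a low p were Yipf3 (0.28, adjusted p = 0.0279), the fatty acid enzyme Tecr (0.35), the hypoxia-inducible factor subunit Hif3a (0.44) and the initiation factor subunit Eif3j2 (-0.90). DESeq2 called 473. In placenta edgeR called 0 genes, with 1108 at an unadjusted p under 0.05, and DESeq2 called 8, the lowest adjusted p in edgeR being 0.531. Eif3j2 was the only gene among the 5 with the lowest p in both tissues, at -0.71 in placenta, where it did not pass (adjusted p = 0.531). All 24 placentas were in lane 1.

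The authors' deposited table for liver GF against control lists 734 genes at an adjusted p under 0.05, and 176 of the 179 called by edgeR are among them with the same direction once the sign is turned. In all 6 of these tables the sign is opposite to the contrasts here (Spearman correlation -0.949 to -0.985 with the fits), so their direction was inferred and signs are given turned. For liver GF against in vivo the authors' deposited table lists 2007 genes, which include 1568 of the 1609, and for liver control against in vivo it lists 607 where edgeR called 0. For placenta the authors' deposited tables list 87 genes for GF against control, 18 for control against in vivo (all 3 called by edgeR among them) and 533 for GF against in vivo (19 of 21). Plac1 is lower in GF than control placentas in the authors' deposited table (log2 fold change -0.36 with the sign turned, adjusted p = 0.0455).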

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

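Chosen only after the result was seen were the tests of the length trend in liver, the Alb to Afp ratio, the match of liver and placenta numbers, the exchanged numbers, the shared chromosome, the title prefix, the overlap of splits with the groups and the correlation with the yolk sac score, and the fits without the length trend or the doubted libraries or with lane as a term for the prefixes.

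In 19 of 218 groups of 6 libraries 1 library lay far from the rest, its gap to the nearest being a large share of the group's range. The limit used would mark about 1 in 20 groups of independent, normally distributed values. It was applied to CPM not on a log scale, and genes of 1 library vary together. The 19 groups therefore cannot be weighed against that rate. Liver control female 6 was the highest of its group in Hipk2 (145.4 CPM against 83.1 next, gap share 0.741), Igf2 (162.5 against 104.2, 0.74), Usp9x (0.746), Mbnl3 (0.734), Fn1 (0.706) and Nr2c2 (0.671). Liver control male 2 was the highest in Atf5 (0.81), Serpina1c (0.709) and Pdrg1 (0.65). Among GF livers male 1 was the highest in Mbnl3 (0.84), and male 2 was the lowest in Thbs1 (0.642) and the highest in Birc5 (0.664). In placenta, control female 4 was the highest in Alb (224.1 CPM against 42.0 next, 0.837), Afp (0.629) and Cubn (0.875), and control female 6 in Prl7a1 (0.662) and Pirb (0.699). GF female 5 was the highest in Prl7a1 (0.667), and GF male 2 the lowest in Igf2r (0.693).

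The effect of GF minus control differed between placenta and liver in 19 genes, 3 of them without a gene name. More negative in placenta were Qprt (difference in log2 fold change -1.56), Klb (-1.48), Slc39a5 (-2.74), Slc36a2 (-2.17), Hgd (-3.30), Slc47a1 (-1.70), Aadac (-3.87), Soat2 (-2.48), Tff3 (-3.63), Fmo4 (-3.44), Amn (-4.16), Agt (-3.83) and Prps1l3 (-0.56). More positive were Evpl (1.49), AU020206 (0.844) and Phf14 (0.411). With the conceptus number as a block 1 gene was called. Of these 13 more negative genes 12 went along with the yolk sac endoderm genes: with group and sex removed their correlation with the yolk sac score over the 24 placentas was 0.691 (Klb) to 0.985 (Agt), against 0.00785 for Prps1l3. Chance could not be excluded, since 2 of 40 splits of the conceptuses gave as many genes, the highest other split giving 36.

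Other splits of the same libraries, with the real one counted, show how often another grouping reached the same count. With 40 splits the smallest share that can be reached is 1 in 40, and the number of such tests was not corrected for. Splits for the groups and prefixes were also drawn without keeping the sexes balanced, as the real groups are. The splits therefore do not exclude chance. Only the real split of 40 reached the count in liver GF minus control (1 split, 179 genes against 0 in the highest other), liver GF minus in vivo (1, 1609 against 540), placenta GF minus in vivo (1, 21 against 0) and the title prefixes in liver (1, 44 against 5), where prefix is largely confounded with lane and a fit with lane as a term called 1 gene. In placenta control minus in vivo 3 of 40 splits were as large (3 genes against 6 in the highest other). A count of 0 is reached by every split, so the splits say nothing about chance for liver control minus in vivo, placenta GF minus control and the prefixes in placenta (40 of 40 by construction, highest other 1, 1 and 2), nor for the sex interactions (20 of 20). For the interactions the highest other splits gave 0, 1 and 203 genes in liver and 0, 1088 and 1 in placenta, for GF minus control, control minus in vivo and GF minus in vivo. The splits with 203 and 1088 genes, where the real one gave 0, show that another grouping of these libraries can call many genes. The reason was not tested. Those splits left 8 and 12 of 18 libraries in their real group, and the split with 540 genes left 10, where the median of the other splits was 10 in each of the 3 cases.

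Counts of lists past the preset camera test could all arise by chance. For liver, 33 of 40 splits gave as many for GF minus control (7 lists, highest other 21), 35 for GF minus in vivo (6, highest other 18) and 5 for control minus in vivo (18, highest other 20). For placenta these were 23 (9 and 21), 21 (11 and 20) and 38 (5 and 21).

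The 1609 genes of liver GF minus in vivo were weighed against 4 technical explanations. With each library's length trend removed 72.4% of them were called again in the same direction, and without the 3 doubted livers 74.6%. These values argue against either as the whole cause. The share was 86% with lane as a term and 72.8% against in vivo livers of prefix G, the prefix of the GF livers. Among GF and control livers lane went with sex, so the lane term rests on in vivo livers. There lane is largely confounded with prefix, so the fits do not separate lane from prefix, and no conclusion is drawn on either. The genes were chosen as called in the same libraries that each fit reuses, so all of these shares may be too high. Part of the calls may still go with any of the 4 explanations, and against prefix A alone 21.9% were called again. Culture, transfer and litter cannot be separated by the labels and stay open as untested.

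Yolk sac and hepatocyte type genes lay lower in GF than control placentas. Liver carried into the samples would bring albumin, but the log2 ratio of Alb to Afp in control placentas was -5.59 (SD 0.571, n = 6), a difference of -5.63 from the livers, which argues against it. A transcript length trend left 98.1% of the list's median, which argues against that too. With alternate members of the yolk sac list as a term, the median of the others went from -3.28 to -0.45, 13.8% of its size. A varying amount of 1 endoderm-type tissue and a joint change in the regulation of these genes would both give this, so the 2 cannot be told apart, and 10 of the list's genes stand on other lists.

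Of 24 placentas 15 matched their same-numbered liver best, against at most 8 in 99 random pairings, so the number likely marks 1 conceptus. The other 9 matched another liver best, among them GF female 4 with liver GF female 6 (correlation 0.783 against -0.03 with its own number) and control male 2 with liver in vivo female 5 (0.652 against 0.429), for which no exchange was tested. Placentas of 3 in vivo females pointed to each other's livers in a closed exchange: on 200 genes not used to find them, placentas 6, A4 and A5 correlated with livers A5, 6 and A4 above those of their own number by at least 0.511, so these numbers may have been exchanged within the in vivo group. Such an exchange would cross the title prefixes, so the results of each prefix alone and of the prefixes against each other (44 genes in liver) would change in the tissue with the wrong numbers. A single chromosome did not carry the match, since at most 11 of 100 matching genes lay on 1 chromosome, which is 11%. Whether a cell type carried it was not tested. No biological explanation beyond a shared conceptus was tested.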

How the results depend on the processing

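The fits without the length trend, without the doubted libraries, with a yolk sac score, and with lane as a term for the prefixes, were chosen after the data were seen. Of 97 called named genes, 0 turned direction in any setting. These genes were chosen as called in the same libraries that each setting refits, so this says little about how firm they are. In liver GF minus in vivo the call held in 5 of 14 settings (Hsd17b13) to 13 of 14 (Vps33a). Among other settings 86 counts were within 1.5 times the count first given, 23 were higher and 27 lower. The 86 include counts of 0 that stayed at 0, such as those of placenta GF minus control, so they overstate how stable the other counts were. The cause was not tested for any changed value below, apart from fewer libraries where 1 sex, 1 prefix or 2 groups were used.

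Liver GF minus control (179 genes) gave 5 at an absolute log2 fold change of 1 or more, 679 with DESeq2, 35 with no filter, 0 with only the 2 groups, 318 with in vivo prefix G only, 16 in males, 0 in females, 349 with the length trend removed and 72 without the doubted libraries. Leaving out 1 library gave 17 (without control 5) to 366 (without GF 6). Liver control minus in vivo (0) gave 164 with DESeq2, 2 with prefix A only and 1 without the doubted libraries, and 0 to 2 without 1 library (2 without in vivo 6). Liver GF minus in vivo (1609) gave 27 at the fold limit, 904 with no filter, 380 with prefix A only, 403 in males and 0 in females, and 820 (without GF 3) to 2343 (without GF 2).

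Placenta GF minus control gave 0 under each alternative run, 0 to 0 without 1 library. Placenta control minus in vivo (3) gave 78 with DESeq2, 1 with the stricter filter, 9 with prefix G only, 0 with prefix A only, 9 with prefix G only and the number as a block together, 0 in males and 0 in females, and 0 (without control 6) to 7 (without in vivo A6). Placenta GF minus in vivo (21) gave 10 at the fold limit, 807 with DESeq2, 53 with only the 2 groups, 1 with prefix A only, 149 with prefix G only and the number as a block together (25 with prefix G only), 0 in males, 0 in females, 8 with the length trend removed and 2 with the yolk sac score, and 9 (without GF 2) to 50 (without in vivo A6). Its share of higher genes was 80% of 25 with DESeq2's size factors in edgeR.

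Of 36 correlations between same-numbered libraries of different groups, 7 were over 0.1 (range -0.324 to 0.393). Differently numbered libraries were not correlated for comparison, so these values do not settle whether the numbers pair libraries of different groups. With prefix G only and the number as a block together, liver GF minus control gave 136 genes and liver GF minus in vivo 1880, where prefix G only gave 318 and 1955.

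Sex interactions (0) gave, with DESeq2, 4 (control minus in vivo) and 2 (GF minus in vivo) in liver and 63 (GF minus control), 164 (control minus in vivo) and 1 (GF minus in vivo) in placenta. With prefix G only they gave 3 (GF minus control) and 2 (control minus in vivo) in liver. DESeq2 gave 473 genes for the prefixes in liver (44) and 8 in placenta (0), and lane as a term gave 1 in liver, where prefix and lane are largely confounded. The tissue difference (19) gave 1 with the conceptus number as a block and 506 with DESeq2. With an estimated correlation 0 of 31 liver and 0 of 25 placenta list results passed. The direction of the oxidative phosphorylation list in liver GF minus in vivo reversed with prefix G only (adjusted p = 0.953). Genes shared by both culture groups in placenta (3) were 6 with prefix G only and 0 and 1 with the in vivo libraries divided. In simulated data 38.8% of genes changed 1.5-fold were called in placenta GF minus control, and smaller changes were not simulated.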

Other observations

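The genes in this part were chosen after their values were seen. In 3 livers genes of pancreas and gut were high: Cpa1 was at 60.5 CPM in in vivo male 1, 29.2 in control male 1 and 69.5 in in vivo male A2. The first principal component of liver, with 23.96% of the variance, was led by Islr2 and Epcam, and that of placenta, with 20.24%, was led by Afp and Apoa1. Xist in male placentas reached 12.9 CPM, against at most 0.163 in male livers.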
